A study of Mus musculus with 7 samples.

How the data were processed

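RNA was read from 7 libraries of bead-isolated kidney endothelial cells, 4 mutant and 3 wildtype, and groups were taken from the sample titles. Per the labels' protocols, mRNA was selected with oligo(dT) beads, made into stranded libraries and read as paired ends. The submitters' processing notes name Trimmomatic 0.39, Bowtie2 2.3.4.1, RSEM 1.2.28 and the mm10 build, with no role or order. The deposited values are FPKM, fragments per kilobase of transcript scaled to the fragments of the library, per the file headers. Whether counting used strand, which annotation it used and what scaling between libraries was applied are not given in the sources used here. Antisense and overlapping genes, and close copies such as Hspa1a and Hspa1b, may share reads.

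The deposited table held 27014 entries. The 429 entries without a gene name, which took 18.35 to 29.26% of a library's FPKM, were left out, and 27 symbols found on 2 entries were summed, which left 26558 genes. No column was left unmapped to a sample. Of the symbols 84.5% were found in GENCODE M21, which gave the coordinates, counted from 1. Mitochondrially encoded genes matched no entry, so that list was not analysed here. Micro and small nucleolar RNA genes, 789 in all, took 3.97 to 17.87% of the named FPKM, and poly(A) selection and short length make their values uncertain.

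FPKM values hold no read totals. Among entries under an FPKM of 0.3, the ratio of a library's value to that of wildtype 1 fell within 0.01 (log2) of a ratio of up to 4 whole reads for 34.0 to 38.7% of entries, against 2.3 to 3.1% at shifted ratios. This gave relative depths of 0.869 and 0.711 for wildtype 2 and 3, and 0.805, 0.826, 0.853 and 0.891 for mutant 1 to 4, with wildtype 1 at 1.0. Too few entries fell on whole reads for counts to be recovered, so no count model was used and absolute depth is unknown. No pair of libraries held the same values: correlations of log2 values over genes were 0.947 to 0.979 within groups, and genes are not independent replicates.

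Genes with a mean FPKM of at least 1 over all libraries, 13420 in number, were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (a linear model per gene, empirical Bayes with an intensity trend). Benjamini-Hochberg adjusted p under 0.05 counted as a call, and all tests were two-sided. Fold changes are on the log2(FPKM + 1) scale, which understates those of low genes. In fits that left out libraries or the filter, limma met genes with no variance and offset them from 0. Errors beside means are SDs of FPKM. Simulated data kept these means and spreads, with changes placed only in genes above an FPKM of about 5 in wildtype. Recovered were 55.8% of 77 genes changed 1.5-fold, 82.1% of 56 changed 2-fold and 94% of 67 changed 4-fold. The share of genes changed was far below the 16.1% called in the data. The adjustment depends on that share, so these rates do not carry over directly. Over the 13420 genes 8 of 160 calls were false. Recovery of lower genes was not measured. Of 20 random lists 0 were called and of 5 raised lists 5. Genes were simulated as independent of each other, so these list results do not test the preset correlation used below.

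The design, the alternatives, 39 gene lists of 723 distinct genes and the rule for named genes were fixed before the data were examined. List entries were matched by symbol, 15 through another symbol of the same gene, and 22 had no match. Lists with at least 3 tested members were tested with camera (limma) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 38 lists, and again with an estimated correlation and with fry. With an estimated correlation 0 lists were called higher or lower (4 at an unadjusted p under 0.05), and fry, which does not compare a list with other genes, called 4 higher and 2 lower. Members were also adjusted over the list alone. A list score is the mean log2(FPKM + 1) of its tested members in a library, compared between groups by an exact permutation test over all 35 splits, whose smallest possible p is 0.0286. The smallest Benjamini-Hochberg adjusted exact p over the 38 scores was 0.1086.

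Named genes were Vhl, the 12 largest rises and 12 largest falls (adjusted p under 0.05, a mean FPKM of at least 5 in the higher group, no overlap between groups, unnamed models and receptor segments left out), the 4 members of each list with the smallest p, and Pecam1, Cdh5, Kdr, Osm, Osmr, Il6st, Stat3, Icam1, Vcam1 and Vegfa. Of the genes this rule took, 1 is not reported here, which left 165, and the counts over all tested genes include it.

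Alternatives were pseudocounts of 0.1 and 0.5, no filter or a mean FPKM of at least 5, rescaling to the same total, median-of-ratios scaling, quantile normalization, array weights, no trend, a fold of at least 2, the replicate number as a block, and leaving out each library. Added after seeing the data were scaling on the pan-endothelial list, the proximal tubule or collecting duct score as a covariate, and leaving out wildtype 3 and mutant 2 together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.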

Results

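Gene expression was measured by RNA sequencing in endothelial cells taken from the kidneys of 3-month-old male C57BL/6 mice. The cells were isolated with magnetic beads carrying an antibody against Cd31, a surface protein of endothelial cells that some blood cells also carry, and RNA was taken without culture. The 4 mutant libraries came from mice in which Hoxb7-Cre deletes Vhlh, the mouse gene for the von Hippel-Lindau protein, in kidney tubule cells. The 3 wildtype libraries came from mice carrying Hoxb7-Cre-GFP alone. The von Hippel-Lindau protein marks hypoxia-inducible factors for degradation. The comparison asks how kidney endothelial cells differ when the gene is lost in the neighbouring tubules. The labels do not say whether each library is a separate animal, so p-values measure the spread between these libraries. Read totals are not given in the values, which are FPKM. The repeated steps among low values placed the depth of the libraries between 0.711 (wildtype 3) and 1.0 (wildtype 1) relative to wildtype 1, and 13222 to 13337 genes per library reached an FPKM of 1.

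Vhl, at chromosome 6 from 113623959 to 113631633 in the mm10 build, was at an FPKM of 7.24 ± 0.861 (SD, n = 3) in wildtype and 6.00 ± 0.387 (SD, n = 4) in mutant libraries. All 4 mutant values, from 5.57 to 6.41, lay below the 3 wildtype values, from 6.71 to 8.24. The log2 fold change was -0.23 with a standard error of 0.0906, and limma with Benjamini-Hochberg adjustment did not call it (adjusted p = 0.123). The deletion was directed at tubule cells, so this level is no check of the mutation in the isolated cells.

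In the mutant isolates the gene lists of injured tubule epithelium, of the response to low oxygen, of glycolysis and of endothelial identity were called higher, and those of MHC class II, of macrophages and dendritic cells and of the interferon responses lower. Across the 38 lists tested, camera with a preset correlation called 11 higher and 6 lower, and with an estimated correlation 0, with 4 at an unadjusted p under 0.05. Of 13420 genes tested, limma with Benjamini-Hochberg adjustment called 1176 higher and 985 lower, 16.1% of the total. Changes of at least 2-fold were fewer among the higher genes, 118, than among the lower, 360. The groups did not overlap for 31.4% of genes, where chance gives 5.7%. The first principal component held 40.9% of the variance and separated the groups, with wildtype libraries from -35.06 to -24.39 and mutant libraries from 16.97 to 32.92. Of all calls 54.4% were higher, and 42.3% were higher both after rescaling each library to the same total and after median-of-ratios scaling. The first of these lowered the higher count to 587. Leaving out wildtype 2 lowered the counts to 321 higher and 521 lower, and leaving out wildtype 3 to 462 and 616. The higher count was also over 1.5 times smaller without wildtype 1 (723), mutant 1 (606) or mutant 2 (694).

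The largest rises included those of adhesion molecules and secreted proteins. Sele, the E-selectin that catches leukocytes on activated endothelium, rose from an FPKM of 4.58 ± 1.26 (SD, n = 3) to 61.3 ± 41.3 (SD, n = 4), a log2 fold change of 3.22 (standard error 0.539, limma adjusted p = 0.00778). Selp, the P-selectin, rose by 2.46. Lcn2 rose from 4.72 ± 0.610 to 51.5 ± 22.7, and Lrg1, a secreted glycoprotein induced by gp130 cytokines, from 3.70 ± 0.897 to 31.6 ± 14.3. Il6, the cytokine interleukin 6, rose from 6.37 ± 1.99 to 55.0 ± 36.1. Spp1, osteopontin, reached 1582 ± 765 from 213 ± 19.2. Serpine2, a protease inhibitor, rose from 19.6 ± 1.42 to 105 ± 9.16. Adamts4, Cyp1a1, Krt19 and AA467197 were also among the largest rises, with log2 fold changes from 2.16 to 2.72. Sele was uneven among mutants, at 91.5 and 102 in mutant 1 and mutant 2 and at 22.6 and 29.0 in mutant 3 and mutant 4. The call was lost without wildtype 1 or wildtype 3 for Selp (largest limma adjusted p = 0.0689), and for Il6 without any 1 of the wildtype libraries (0.0697). It was lost without any library except mutant 3 or mutant 4 for Adamts4 (0.0796), and without any wildtype library or mutant 1 for AA467197 (0.0872).

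**Figure D1:**
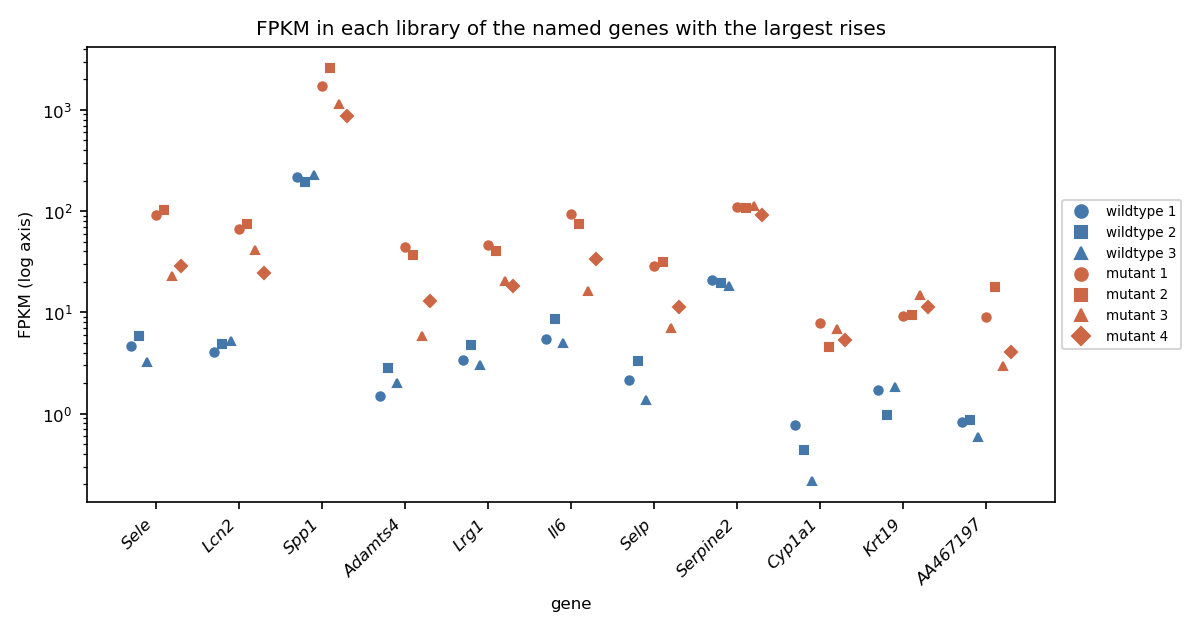
FPKM on a log axis of the 11 reported genes with the largest rises, 1 point per library, 3 wildtype libraries in blue and 4 mutant libraries in orange. For Sele the mutant points run from 22.6 to 102 and the wildtype points from 3.26 to 5.78.

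Genes of antigen presentation and of macrophages were among the largest falls. Cd74, the chain that escorts MHC class II molecules, fell from an FPKM of 6479 ± 994 (SD, n = 3) to 1238 ± 171 (SD, n = 4), a log2 fold change of -2.39 (standard error 0.157, limma adjusted p = 6e-04). H2-Aa fell from 3358 ± 440 to 712 ± 104, H2-Ab1 from 2370 ± 326 to 478 ± 78.3, and H2-Eb1 from 1905 ± 256 to 369 ± 66.6. C1qc, a chain of complement C1q made by macrophages, fell from 506 ± 140 to 104 ± 42.9. Lilra5, Mgl2, Sap25, Asb2, H2-DMa and Siglece had log2 fold changes from -2.79 to -2.23, and the Sap25 call was lost without wildtype 2, wildtype 3 or mutant 1 (largest limma adjusted p = 0.0846). Mir5107, a microRNA gene, is listed at 0 in all 4 mutant libraries and at 330.4, 926 and 680.04 in wildtype 1 to 3. Its positions 60812076 to 60812163 on chromosome 18 lie inside Cd74, at 60803848 to 60812652 on the same strand, so its reads cannot be told from those of Cd74.

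**Figure D2:**
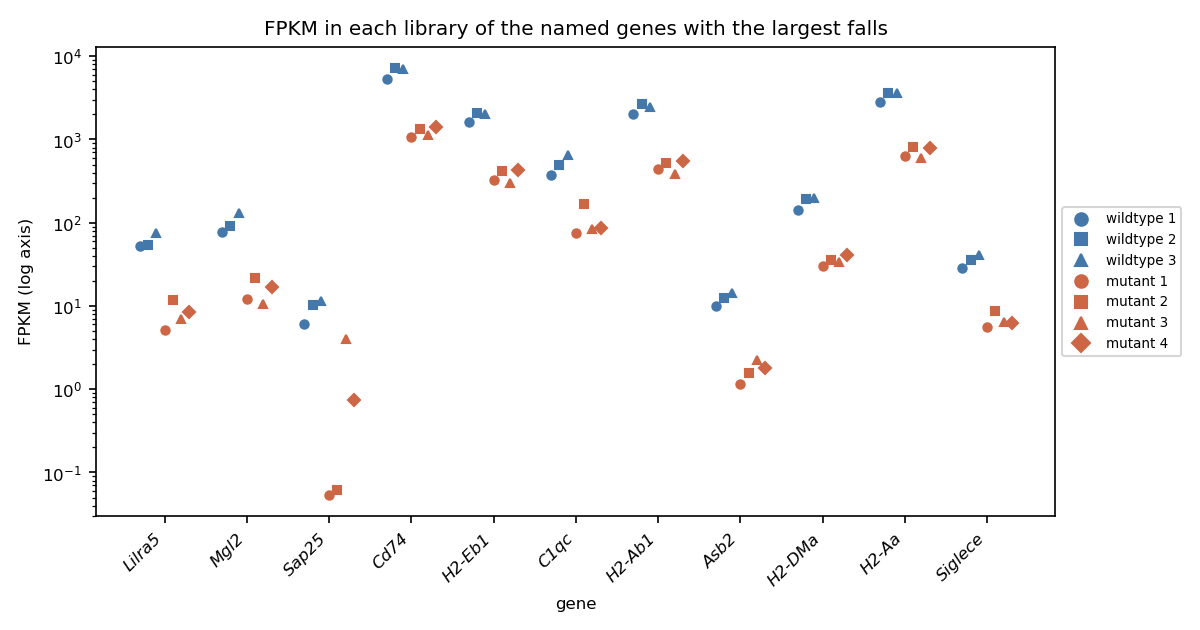
FPKM on a log axis of the named genes with the largest falls other than Mir5107, 1 point per library, 3 wildtype libraries in blue and 4 mutant libraries in orange. Mean Cd74 is 6479 in wildtype and 1238 in mutant libraries.

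All 8 tested genes of the MHC class II list fell, with a median log2 fold change of -2.27, and the count was 8 adjusted over the list alone. Of 28 tested macrophage and dendritic cell markers 21 fell and 1 rose (22 and 1 adjusted over the list alone), with a median of -1.65. Among them C1qa had a log2 fold change of -2.14 and Emr1, the F4/80 antigen, of -2.22, while Plac8, a gene also high in monocytes, rose by 0.90. Camera with a preset correlation called both lists lower (adjusted p = 1.3e-12 and 1.17e-12), and with an estimated correlation the adjusted p was 0.178 and 0.708. The phagocyte score, the mean log2 value over the list, was 5.94 in mutant 2 and 4.97 to 5.09 in the other mutants, against 6.46 to 6.92 in wildtype. Of the type I interferon list 7 of 26 genes fell (7 adjusted over the list alone, median -0.25), among them the antiviral genes Oas2 (log2 fold change -1.89) and Mx1 (-1.82), and without wildtype 1, 2 or 3 the count was 4. Of the MHC class I and interferon gamma list 6 of 30 fell and 1 rose (6 and 1 adjusted over the list alone, median -0.10). Among the lower genes were Nlrc5, the activator of MHC class I genes (-0.71), Irf8 (-0.94) and Ciita, which is also in the MHC class II list. Camera called both interferon lists lower as well (adjusted p = 0.000149 and 0.0137), with 0.757 and 0.798 as adjusted p with an estimated correlation, and the call of the MHC class I list ended without mutant 3 (0.0783). Of 10 B and plasma cell markers 2 fell, Cd79b and Igj (2 adjusted over the list alone; camera adjusted p = 0.0183, and adjusted p = 0.757 with an estimated correlation). The list was not called without wildtype 2 (0.0878) or mutant 2 (0.0541), nor with a mean FPKM of at least 5 (0.0965). The call was lost without any library except mutant 3 for Cd79b (largest limma adjusted p = 0.139) and without any except mutant 4 for Igj (0.143).

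Genes induced by hypoxia-inducible factors and genes of glycolysis were higher in every mutant library than in any wildtype library when averaged over each list. Of 30 tested hypoxia genes 13 rose and 1 fell (19 and 1 adjusted over the list alone), with a median log2 fold change of 0.52. Bnip3, a mitophagy receptor, rose from an FPKM of 20.4 ± 2.74 (SD, n = 3) to 43.3 ± 4.22 (SD, n = 4). Vegfa, the main growth factor for endothelial cells, rose from 24.3 ± 3.30 to 41.1 ± 6.26, a call lost without wildtype 2 (limma adjusted p = 0.0602). Plod2, a collagen-modifying enzyme, rose by 0.75 and Ero1l, an oxidase of the endoplasmic reticulum, by 0.71. Pfkfb4 fell from 12.5 ± 1.81 to 3.19 ± 0.512. Of 20 glycolysis genes 12 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 0.49. Ldha, lactate dehydrogenase A, rose from 148 ± 6.98 to 227 ± 5.82, and Pgk1 from 88.7 ± 13.3 to 150 ± 14.6. Camera called both lists higher (adjusted p = 6.46e-07 and 2.58e-06), and the adjusted p with an estimated correlation was 0.0747 and 0.448. After scaling the libraries on the pan-endothelial list, a setting chosen after seeing the data, 2 hypoxia genes and 0 glycolysis genes were called higher. Rescaling to the same total left 5 glycolysis genes called, leaving out wildtype 2 left 8 hypoxia and 5 glycolysis genes, and leaving out wildtype 3 left 7 glycolysis genes.

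Some general endothelial markers were also called higher. Of 25 pan-endothelial genes 8 rose and 0 fell (14 adjusted over the list alone), with a median log2 fold change of 0.38. Vwf, von Willebrand factor, rose from an FPKM of 6.12 ± 1.27 (SD, n = 3) to 13.5 ± 2.72 (SD, n = 4), and Cd93 by 0.84. Pecam1, the gene for Cd31, rose by 0.53 and Cdh5, the junction protein VE-cadherin, by 0.56. Both calls were lost without wildtype 2, wildtype 3, mutant 1, mutant 2 or mutant 4, with largest limma adjusted p of 0.115 and 0.094 without wildtype 2, and without these libraries the list held 2, 4, 3, 4 and 3 calls. Both were also lost after rescaling to the same total (0.072 and 0.0607), with quantile normalization (0.0596 and 0.0634) and with no filter (0.0691 and 0.0525). The list held 3 calls after that rescaling, 4 with quantile normalization and 1 after scaling on itself. Kdr, a receptor for Vegfa, was at 189 ± 43.8 and 192 ± 34.3 (adjusted p = 0.926). Of 13 venous and ascending vasa recta genes 6 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.58), with Cd9 up by 0.68 and Nr2f2, the venous transcription factor, by 0.75. Of 28 tip cell and angiogenesis genes 8 rose and 2 fell (11 and 2 adjusted over the list alone; median 0.39), and Cd34 rose from 145 ± 28.1 to 322 ± 9.07, Col4a2 by 1.08 and Sparc by 1.14. Camera called the 3 lists higher (adjusted p = 0.000131, 0.0124 and 0.0104), and the adjusted p was 0.757 for each with an estimated correlation. The venous count was 3 without wildtype 2, mutant 1, mutant 2 or mutant 4 and 2 without wildtype 3. The pan-endothelial score was lowest in wildtype 3, at 6.27, and 6.65 to 7.01 elsewhere. Of the arterial list 0 of 18 genes were called (median 0.17), with 4 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Of the glomerular list 2 of 13 rose (4 adjusted over the list alone; median 0.005, with a negative sign under 3 other scalings), and of the lymphatic list 2 of 7 (2 adjusted over the list alone; median 0.29). Camera called none of these 3 (adjusted p = 0.599, 0.775 and 0.0545), and called the lymphatic list higher without wildtype 1 (0.0361), wildtype 2 (0.0165), mutant 3 (0.0413) or mutant 4 (0.0274), after rescaling to the same total (0.0345) or median-of-ratios scaling (0.0347), with no filter (0.0457) and with the replicate block (0.0088). The lymphatic count was 0 without wildtype 2 or mutant 1 and 1 without wildtype 3, mutant 2, mutant 3 or mutant 4, and the glomerular count 0 without wildtype 2 and 1 without wildtype 3.

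Receptors and targets of oncostatin M, a cytokine of the interleukin 6 family that signals through gp130, were called higher as a list. Of 29 genes 9 rose, 3 fell and 17 were not called (15 higher and 4 lower adjusted over the list alone), with a median log2 fold change of 0.54. The score was 4.33 in mutant 3, inside the wildtype range of 4.13 to 4.36, and 4.57 to 5.24 in the other mutants. Mt2, a metallothionein, rose from an FPKM of 51.8 ± 12.5 (SD, n = 3) to 132 ± 28.3 (SD, n = 4), Osmr, the receptor of oncostatin M, by 0.79, Il6st, gp130 itself, by 0.54, and Stat3 by 0.61. Il6ra, the interleukin 6 receptor, fell by 1.36. Osm was at 17.2 ± 4.26 and 9.35 ± 8.62 and was not called (limma adjusted p = 0.172). Mutant 2 was at 22.28 and the other mutants at 4.77 to 5.54, and without mutant 2 the mutant mean was 5.04 and the gene was called lower (log2 fold change -1.56, limma adjusted p = 0.00238). It was also called after scaling on the pan-endothelial list (0.0439). Camera called the list higher (adjusted p = 0.0243, and adjusted p = 0.836 with an estimated correlation), and the call ended without mutant 2 (0.146), mutant 1 (0.0709) or wildtype 1 (0.0707) and with a mean FPKM of at least 5 (0.0634). Higher genes of the list numbered 5, 3 and 3 without wildtype 1, 2 and 3, 5 and 4 without mutant 1 and 2, and 15 without mutant 3. Without wildtype 2, wildtype 3 or mutant 2 the calls of Osmr (largest limma adjusted p = 0.0928) and Il6st (0.107) were lost, for Il6st also without mutant 1, and Stat3 lost its call without any library except mutant 3 (0.129). Median-of-ratios scaling and quantile normalization also ended the calls of Il6st (0.0517 and 0.0573) and Stat3 (0.0734 and 0.0699), and rescaling to the same total that of Il6st (0.068). In the leukocyte adhesion list 4 of 17 rose and 2 fell (6 and 2 adjusted over the list alone; median 0.42, camera adjusted p = 0.244, and 0.0355 without mutant 3), and 2 rose without wildtype 1 or wildtype 3. Icam1, an adhesion molecule, rose from 64.9 ± 7.79 to 172 ± 66.7 (limma adjusted p = 0.0391), a call lost without any library except mutant 3 (0.121) and under median-of-ratios scaling (0.0518). Vcam1 had a log2 fold change of 1.19 and was not called (limma adjusted p = 0.0587), but was called higher without mutant 3 (0.00658), after rescaling to the same total (0.045) and with array weights (0.00599). Selplg, the selectin ligand of leukocytes, fell by 1.07 and the chemokine Cxcl9 had a log2 fold change of -1.69. The NF-kB and TNF list was not called (2 of 24 rose, 1 fell; 3 and 4 adjusted over the list alone; camera adjusted p = 0.599, and 0.0429 with 6 higher genes without mutant 3, against 1 without any other library), and Tnf fell by 1.30, a call lost without any library except mutant 2 or mutant 3 (0.164) and under median-of-ratios scaling (0.0522). Of the complement and coagulation list 8 of 22 rose and 4 fell (12 and 4 adjusted over the list alone; camera adjusted p = 0.131), with Procr, the endothelial protein C receptor, up by 1.05. That list was called higher without mutant 3 (0.0299), after rescaling to the same total (0.0364) and with the replicate block (0.0174), and held 3 higher genes without wildtype 2 or wildtype 3.

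**Figure D3:**
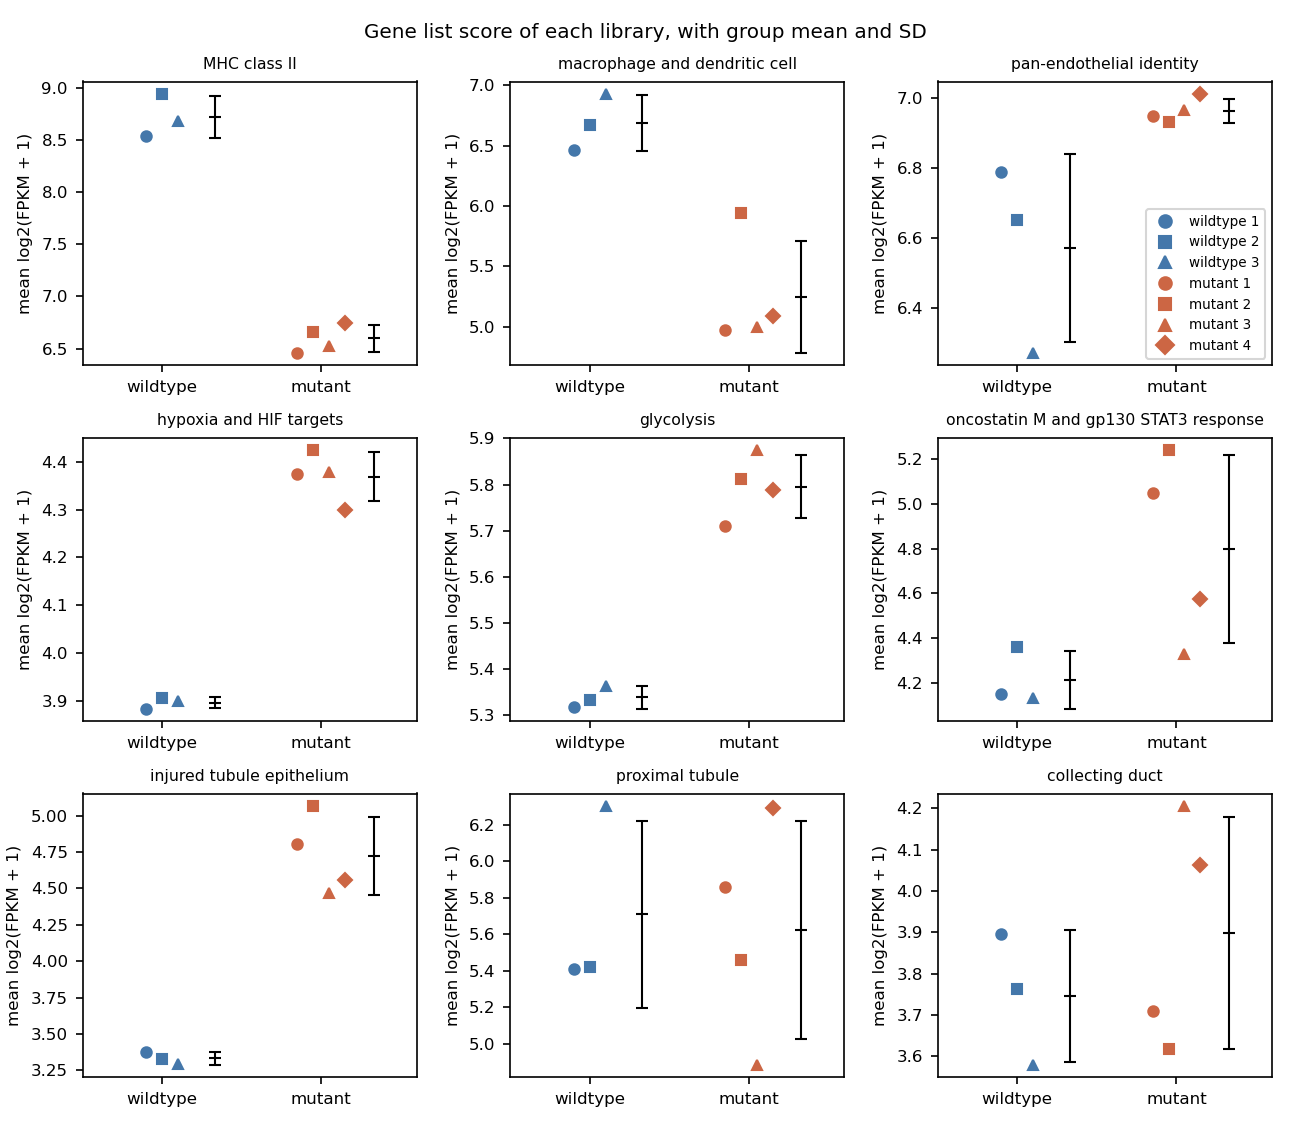
Score of each library, the mean log2(FPKM + 1) over the tested members, for 9 gene lists, with the mean and SD of 3 wildtype (blue) and 4 mutant (orange) libraries beside the points. MHC class II scores run from 6.46 to 6.74 in mutants and from 8.54 to 8.94 in wildtype, and proximal tubule scores overlap.

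Matrix genes rose in part. Of 28 extracellular matrix genes 5 rose and 1 fell (7 and 1 adjusted over the list alone), with a median log2 fold change of 0.56, and Col18a1 rose by 0.80 and Col5a2 by 0.79. Camera called the list higher (adjusted p = 0.00027, and adjusted p = 0.76 with an estimated correlation). The higher count was 2 without wildtype 1 or 3, 3 without wildtype 2 or mutant 1 and 8 without mutant 3. Of 26 genes of endothelial-mesenchymal transition 5 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.214, and 0.0306 with the replicate block), and 2 rose without wildtype 3 and 3 without wildtype 1, wildtype 2, mutant 1 or mutant 2, while 1 fell without wildtype 2 or mutant 4. In that list 2 rose and 2 fell after rescaling to the same total, 3 rose with quantile normalization, and 2 rose and 6 fell after scaling on the pan-endothelial list. Among these Snai1, a transcription factor of the transition, rose from an FPKM of 2.97 ± 0.563 (SD, n = 3) to 11.8 ± 4.09 (SD, n = 4) and Tgfbr1 fell by 1.31. Neither the TGF-beta and BMP list (3 of 24 rose, 2 fell; 4 and 2 adjusted over the list alone; camera adjusted p = 0.783) nor the Notch list (1 of 16 rose, 3 fell; 1 and 3 adjusted over the list alone; 0.162) was called. The TGF-beta and BMP list held 0 higher genes without wildtype 2, wildtype 3, mutant 1 or mutant 2 and after rescaling to the same total, and 1 lower gene without any library except mutant 2. The Notch list was called lower without wildtype 3 (0.0324), and Notch2 fell by 0.70 and Rbpj, the transcription factor of the pathway, had a log2 fold change of -1.03. Of 21 fatty acid genes 9 rose and 1 fell (12 and 2 adjusted over the list alone; median 0.33) and of 29 oxidative phosphorylation genes 1 rose and 0 fell (1 adjusted over the list alone; median 0.23). Both were called higher (camera adjusted p = 0.013 and 0.00134; adjusted p = 0.757 and 0.798 with an estimated correlation), and both medians turned negative, at -0.07 and -0.18, after scaling on the pan-endothelial list. The fatty acid list was not called without mutant 4 (0.0502) or with the replicate block (0.0576), and its higher genes numbered 4, 0 and 5 without wildtype 1, 2 and 3, 4 and 5 without mutant 1 and 2, 6 without mutant 3 and 5 without mutant 4. They numbered 4 after rescaling to the same total and 0, with 3 lower, after scaling on the pan-endothelial list. Cytosolic ribosomal protein genes were called lower as a list (4 of 30 fell, 3 adjusted over the list alone, 0 or 1 without any library except mutant 3; 0 after rescaling to the same total, 2 with quantile normalization and 21 after scaling on the pan-endothelial list; median -0.16; camera adjusted p = 0.00022, and adjusted p = 0.781 with an estimated correlation). The cell cycle (0 of 20 called by limma, 3 at an unadjusted p under 0.05, 0 adjusted over the list alone), p53 (3 of 17 rose, 1 fell; 3 and 1 adjusted over the list alone) and immediate early lists (2 of 26 rose, 1 fell; 2 and 3 adjusted over the list alone) were not called, with camera adjusted p of 0.116, 0.162 and 0.561. The cell cycle list was called higher without wildtype 3 (0.00741) or mutant 3 (0.00801), after rescaling to the same total (0.0433), with no filter (0.0388) and with array weights (0.00379), and the immediate early list held 4 higher genes without mutant 3 and 1 without any other library.

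Markers of other cells of the kidney and blood were read in these isolates. Of 11 genes of injured tubule epithelium 8 rose and 0 fell (10 adjusted over the list alone), with a median log2 fold change of 1.19. Clu, clusterin, rose from an FPKM of 42.7 ± 6.96 (SD, n = 3) to 123 ± 26.9 (SD, n = 4) and the keratin Krt19 from 1.51 ± 0.460 to 11.1 ± 2.69. Camera called the list higher (adjusted p = 2.86e-05, and adjusted p = 0.118 with an estimated correlation). Without 1 library 4 genes (wildtype 3 or mutant 1) or 5 (wildtype 1, wildtype 2 or mutant 4) were called. Camera called none of the lists of intact tubule segments: 0 of 25 proximal tubule genes were called (1 higher and 1 lower at an unadjusted p under 0.05, 0 adjusted over the list alone; median -0.09, camera adjusted p = 0.599), 3 of 13 thick ascending limb and distal tubule genes rose and 1 fell (8 and 1 adjusted over the list alone; 0.0634), and 4 of 18 collecting duct genes rose and 1 fell (8 and 2 adjusted over the list alone; 0.244). The distal list was called higher without wildtype 3 (0.0343) or mutant 2 (0.0141), after rescaling to the same total (0.0345) or median-of-ratios scaling (0.0328) and with no filter (0.0389), and held 1 higher gene without wildtype 1 or wildtype 2 and 0 lower without any library except mutant 2. The collecting duct list held 2 higher genes without wildtype 2 or wildtype 3, 4 higher and 6 lower without mutant 3, and 0 lower without wildtype 1, wildtype 2, mutant 1, mutant 2 or mutant 4. The distal transporter Slc12a3 rose by 0.84, and the keratins Krt8 and Krt18 of the collecting duct list by 0.77 and 0.94. The proximal tubule score ran from 4.89 (mutant 3) to 6.30 (wildtype 3). Podocyte (1 of 5 rose, 2 fell; 1 and 2 adjusted over the list alone), pericyte and smooth muscle (2 of 15 rose, 2 fell; 2 and 3) and fibroblast lists (0 of 8 rose, 1 fell; 0 and 1) were not called, with camera adjusted p of 0.655, 0.526 and 0.981. The podocyte median was 0.16 where camera's direction was lower. In these, Ptpro, a podocyte phosphatase, fell by 1.78, and Ren1, renin, rose from 36.7 ± 3.51 to 74.4 ± 14.6. The T and NK cell (2 of 14 rose, 1 fell; 2 and 2 adjusted over the list alone), neutrophil (1 of 9 rose, 1 fell; 1 and 2) and platelet lists (0 of 3 called by limma, 1 at an unadjusted p under 0.05, 0 over the list alone) were not called either, at 0.981, 0.244 and 0.999. The neutrophil list was called lower without mutant 2 (0.00557) and with a mean FPKM of at least 5 (0.0273), and the T and NK cell list held 0 higher genes without wildtype 1, wildtype 2, mutant 1 or mutant 4 and 1 without wildtype 3 or mutant 3. The erythroid list was called higher with 0 of 5 members called over all genes by limma (5 at an unadjusted p under 0.05, 5 adjusted over the list alone; camera adjusted p = 0.041, and adjusted p = 0.757 with an estimated correlation), and not without wildtype 1 (0.0918), wildtype 2 (0.0846), mutant 2 (0.0754) or mutant 4 (0.0502), nor with a mean FPKM of at least 5 (0.0626) or the replicate block (0.0576), and 4 members were called without wildtype 3.

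**Figure D4:**
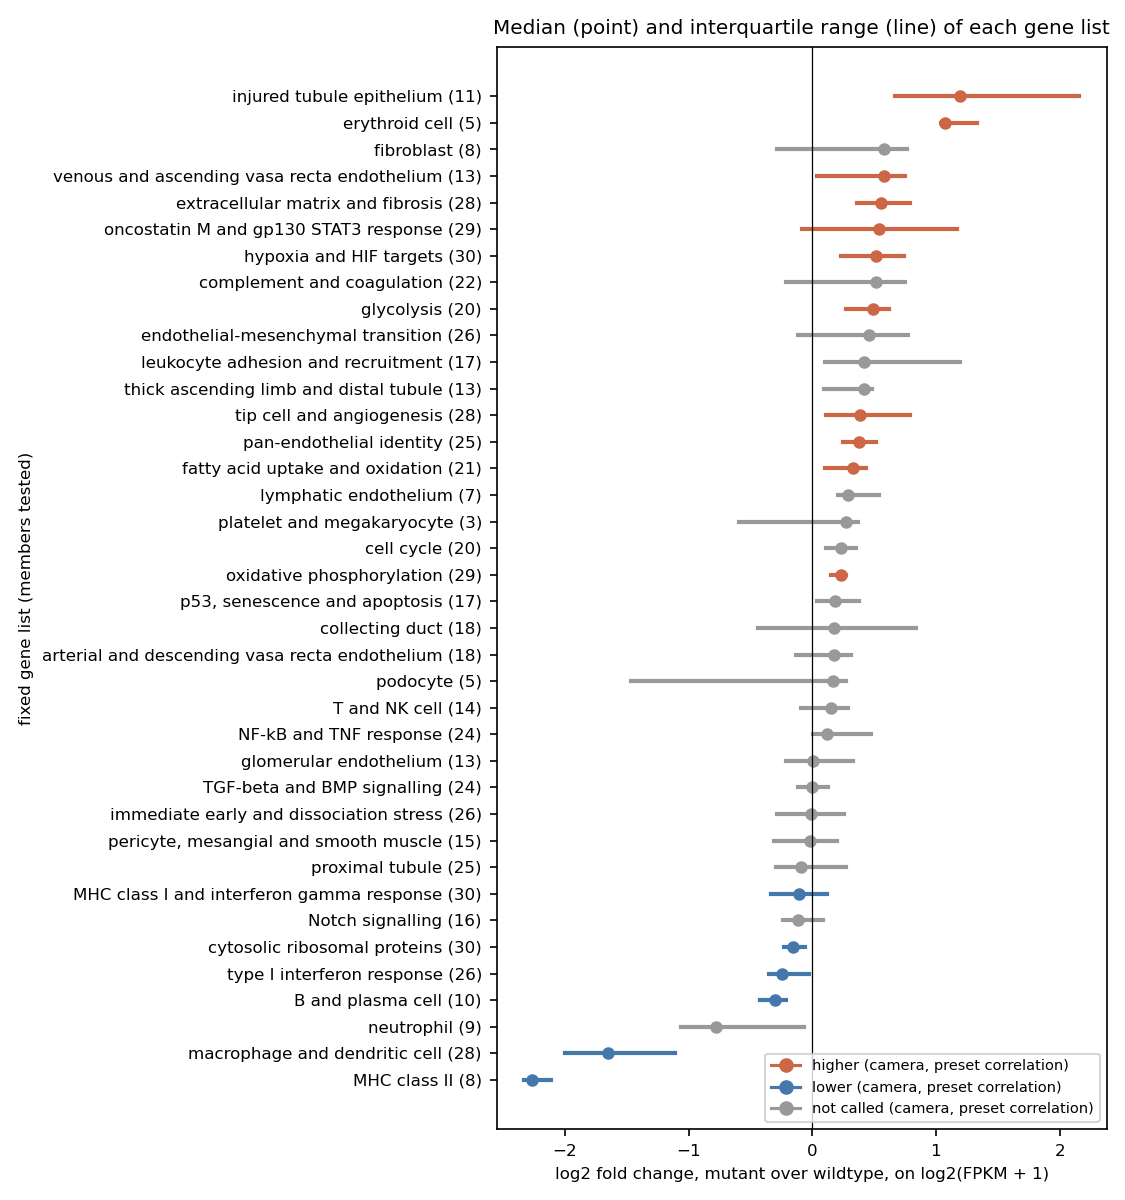
Median log2 fold change (point) and interquartile range (line) of each of the 38 gene lists tested, mutant over wildtype on the log2(FPKM + 1) scale, with the members tested in brackets. Orange and blue mark the 11 lists called higher and the 6 called lower by camera with a preset correlation, and 0 lists were called with an estimated correlation.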

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

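All tests of explanations in this part were chosen after the results they bear on had been seen. Single mutant libraries stood apart from the other 3 in 14 of the values of 165 genes and 38 list scores examined, where chance gives about 1 in 20, or 10.2. A library stood apart when its gap to the nearest of the others, over the range of the 4, passed Dixon's 95% critical value. Wildtype libraries, being 3, were not examined. Mutant 2 was the library apart in 8 of the 14. Its FPKM was 22.28 for Osm (4.77 to 5.54 in the others), 58.08 for the platelet gene Pf4 (7.18 to 8.93) and 16.77 for Ppbp (0.837 to 1.15). Gaps were smaller for Il6ra, at 5.20 (3.03 to 3.21), Pmaip1, at 25.11 (18.8 to 19.2), and Trp53inp1, at 10.17 (10.5). The rule takes no account of the size of a gap. Its scores were 5.938 for macrophages and dendritic cells and 5.835 for platelets. Mutant 1 stood apart for Plat, at 161 (96.4 to 102 in the others), for Lsp1, at 29.47 (37.7 to 38.4), and for the pericyte and smooth muscle score, at 3.404. Mutant 3 stood apart for Krt8, at 57.98 (66.2 to 67.2). Mutant 4 stood apart for Trpm6, at 1.47 (1.21 to 1.24), and the MHC class I and interferon gamma score, at 6.161.

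Of the 35 splits of the 7 libraries into 4 and 3, 1, the real one, gave as many called genes. It called 2161 genes and the highest of the other splits 83. Other splits mix the groups, which adds the group difference to their spread and lowers their counts. With 35 splits the smallest possible exact permutation p is 0.0286, so chance is argued against at that level and is not excluded.

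All 8 MHC class II genes and 21 of 28 phagocyte markers fell, and camera's calls of both lists were lost with an estimated correlation (adjusted p = 0.178 and 0.708). Fry called both lower (fry adjusted p = 0.000241 and 0.0327). Scaling is argued against, since the MHC class II median closest to 0 over 4 scalings was -2.22, and so is a fall of MHC class II in endothelial cells alone, since 20 of 27 phagocyte markers outside the class fell too. Fewer phagocytes carried along in the mutant isolates may account for most of the pattern, with a median log2 fold change of -1.63 over these markers and a mean FPKM of the abundant C1qa of 636 in wildtype and 150 in mutants, and the Cd31 beads would not remove phagocytes that carry Cd31. One shared loss as the whole account is argued against and not excluded. The MHC class II score minus the score of these markers was lower by 0.73 in mutants with no overlap between groups, at 0.889 in mutant 2 and 1.679 to 1.85 in the others (exact permutation p = 0.0571, adjusted 0.0816 over 10 comparisons). Without mutant 2 the difference was -0.51. The markers fell unevenly, with quartiles of -1.96 and -1.10, which limits their mean as a measure of a shared loss. A different mix of phagocytes, or lower MHC class II in the cells left, stays open.

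Of 11 injured tubule genes 8 rose, and of markers of intact segments 0 of 25 proximal tubule, 3 of 13 distal and 4 of 18 collecting duct genes. With an estimated correlation camera's call of the injured tubule list was lost (adjusted p = 0.118), while fry called it higher (fry adjusted p = 0.000498). More tubule RNA of every segment is argued against by the injured tubule score minus the proximal tubule score, higher in mutants by 1.48 with no overlap, and more collecting duct RNA by the score minus the collecting duct score, higher by 1.24 (exact permutation p = 0.0571 each, adjusted 0.0816). RNA from phagocytes is argued against by the score of the 27 phagocyte markers outside MHC class II, lower by 1.40 (difference in mutants -1.401). A changed state of tubule cells carried along at a like share, and expression of these genes by endothelial cells, may both account for the rise and were not told apart by a test.

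Of hypoxia, glycolysis and pan-endothelial genes 13 of 30, 12 of 20 and 8 of 25 rose, and camera's calls of the 3 lists were lost with an estimated correlation (adjusted p = 0.0747, 0.448 and 0.757). Fry, which does not compare a list with other genes, kept the first 2 and not the pan-endothelial list (fry adjusted p = 0.000241, 0.00302 and 0.104). The collecting duct and proximal tubule scores differed little between groups, by 0.15 and -0.09 (exact permutation p = 0.4286 and 0.9143, adjusted 0.5768 and 0.9143). With either score as a covariate, 13 of the 13 hypoxia genes called higher were also called. A score this alike in both groups can remove little of a group difference, so these fits could hardly have ended the calls. They do not bear on a changed state of tubule cells carried along at a like share. Dilution by phagocyte RNA in the wildtype isolates would lower hypoxia and endothelial genes in wildtype alike. The hypoxia and glycolysis scores minus the glomerular score were higher in mutants by 0.37 and 0.35 with no overlap (exact permutation p = 0.0286 each, the smallest possible, adjusted 0.0816). The hypoxia score minus the arterial score was higher by 0.33 with overlap (exact permutation p = 0.1143, adjusted 0.1429). The glomerular list had been seen to be flat (median 0.005), and a changed mix of endothelial cells would give the same difference. Both glomerular differences stayed without overlap when any 1 library was left out, at 0.30 and 0.28 or more. Dilution alone, with no change in that mix, would leave no such difference, so these values argue against it as the whole cause. With a changed mix, dilution may account for part or all of the rise. The hypoxia score minus the pan-endothelial score differed by 0.081 (exact permutation p = 0.6, adjusted 0.6667), the groups overlapping through wildtype 3. Without that library it differed by 0.23 with no overlap. Dilution in part or with a changed mix, a changed state of tubule cells carried along and a response of endothelial cells to the mutation all stay open. The pattern is therefore not called biological here.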

How the results depend on the processing

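Scaling on the pan-endothelial list, the covariates and leaving out wildtype 3 and mutant 2 together were chosen after seeing the data. Counts of 1176 higher and 985 lower genes stayed within 1.5 times under both pseudocounts, both filters, median-of-ratios scaling, quantile normalization, no trend and both covariates. Rescaling to the same total gave 587 higher, array weights 2258 and 1812, and a fold of at least 2 gave 118 and 360. Leaving out 1 library gave 321 (without wildtype 2) to 1205 (without mutant 3) higher and 521 to 1077 lower, 10 to 16 lists higher and 5 to 7 lower, and -0.28 to -0.15 for Vhl. Fewer libraries lower the power of each such fit. Without wildtype 3 and mutant 2 the counts were 274 and 616, with 0 pan-endothelial, 1 venous, 2 oncostatin M, 3 matrix, 4 fatty acid, 4 injured tubule and 5 glycolysis genes higher and 0 ribosomal protein and 4 type I interferon genes lower. Scaling on the pan-endothelial list gave 188 higher and 3783 lower and 20 lists higher, and moved the median of all genes from 0.04 to -0.31, as lowering every mutant library would. Under it Vhl was called lower (-0.59, limma adjusted p = 0.0304, 0.0778 to 0.498 in the other settings), and Smad5 (-0.0784) and Hadha (-0.0431) reversed. Under it 11 list medians changed sign, among them those of the pan-endothelial (-0.03) and NF-kB (-0.28) lists. In the same setting higher and lower genes were 5 and 6 of the oncostatin M list, 5 and 5 of the tip cell list and 1 and 1 of the venous list, 3 and 6 of the complement list, and 18 fell in each interferon list. The proximal tubule median stayed negative, at -0.50, while camera's direction turned from lower to higher (adjusted p = 0.0462). Relative to that shift the hypoxia median was 0.47 and the MHC class II median -2.36. With an estimated correlation camera called 0 lists higher and 0 lower, and fry 4 and 2. The lists fry called were hypoxia, glycolysis, injured tubule and fatty acid (higher), and MHC class II and macrophage and dendritic cell (lower). The replicate numbers gave no sign of pairing (correlations of deviations of same-numbered libraries -0.061, 0.026 and -0.281, and of differently numbered libraries -0.146 to 0.244). So few libraries cannot exclude it. With the number as a block, on replicates 1 to 3, 259 genes were higher and 420 lower, 634 of them shared with the fit of all libraries. Of 165 named genes 124 were called, 74 of them in each fit that left out 1 library. The cause was not tested for array weights or for the rescaling to the same total. Depth was not known in reads, which limits the low genes.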

Other observations

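Gene families, grouped after seeing the data by a shared start of the symbol, were tested with camera at the preset correlation: of 127 families with at least 10 tested genes, 3 were higher and 7 lower, and 0 with an estimated correlation (adjusted p = 0.957 for each). Of the families named here, each median kept its sign under 4 other scalings. Of 20 histone genes 10 fell and 0 rose, with a median log2 fold change of -0.63, and Hist1h2bg fell from a mean FPKM of 18.7 to 8.23. Histone messages of the replication type lack a poly(A) tail, and the libraries were made from poly(A) RNA. Of 10 Toll-like receptor genes 6 fell and 0 rose (median -1.10), Tlr9 from 11.8 to 2.09, and of 19 C-type lectin genes 9 fell (median -0.94). The phagocyte markers outside MHC class II hold 0 genes with these symbol starts, but their list holds the C-type lectin genes Mrc1 and Cd209a. These markers were lower in the same libraries (20 of 27 called, median -1.63). Of 13 claudin genes, whose proteins seal epithelial and endothelial junctions, 6 rose and 0 fell (median 0.44), with Cldn1 up by 0.81 and Cldn4 from 43.1 to 61.5. Of 23 collagen genes 6 rose and 1 fell (median 0.44), with Col4a1 from 138 to 255. Of these collagen genes 14 are in the fixed lists, 12 of them in the extracellular matrix list, so the family in part repeats those lists. Of 10 carbonic anhydrase genes 4 rose (median 0.55), with Car2 from 45.2 to 68.5 and Car9, a classical hypoxia gene, at 1.46 and 2.29 (limma adjusted p = 0.128). Examples were chosen after their values were seen, and no explanation was tested for these families.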
